A study of Mus musculus with 8 samples.

How the data were processed

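Chromatin immunoprecipitation followed by sequencing (ChIP-seq) for histone H3 acetylated at lysine 27 (H3K27ac) was carried out in mpkCCD cells, a mouse cell line of the kidney's cortical collecting duct. The cells had been kept for 24 h with 0.1 nM dDAVP, a vasopressin analogue, or with its vehicle. Per the labels, the series holds 4 immunoprecipitated libraries and 4 input libraries, 1 of each per treatment in each of 2 experiments. Sample titles give the experiment number, which pairs a dDAVP library with a vehicle library, and the number is used here as the replicate number.

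A set of 4 peak lists was used, 1 per immunoprecipitated library. Per the file headers, each list was called with MACS 2.1.1.20160309 in broad mode on 1 immunoprecipitated library against the input of the same treatment and experiment, so replicates had not been pooled. Reads were aligned with BWA to mm10 and handled with SAMtools, per the submitters' processing notes. Per the file headers, the q-value limit was 0.01 for strong regions and 0.1 for broad regions, tags were 50 bp long, at most 1 tag was kept per position, and local background was taken over 1000 bp and 10000 bp. The larger of the 2 data sets in a call was scaled towards the smaller, per the file headers. The pileup column is a signal made by the authors' peak caller, the mean tag coverage of a peak. The fold enrichment column is the authors' ratio of that signal to the local background. The names of 2 further columns had been lost, and their values and order fit the deposited -log10 p-value and -log10 q-value of the caller. Peak names inside both lists of experiment 2 carry the number 3, and the lists were attached to the records of the input libraries, while their names and headers give the immunoprecipitated library. Fold, p-value and q-value are the authors' own values per peak and were used only to describe, rank or filter peaks within a list.

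Depth was read from the file headers. The numbers of immunoprecipitated tags kept were 27923780 for dDAVP replicate 1, 32705755 for vehicle replicate 1, 31676748 for dDAVP replicate 2 and 31283282 for vehicle replicate 2. The inputs held 38291361, 35901413, 30753752 and 35142984 kept tags in the same order. Read counts per region were not used here.

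Peaks on the 19 autosomes and the X and Y chromosomes were kept, and 22, 11, 5 and 12 peaks on other scaffolds were left out of dDAVP replicate 1, vehicle replicate 1, dDAVP replicate 2 and vehicle replicate 2. Overlapping or touching peaks of the 4 lists were merged into union regions, and a list called a region when a peak of it overlapped by at least 1 bp. Regions called in both dDAVP lists and no vehicle list are named dDAVP-only, and the reverse vehicle-only. No test per region was made, because 2 lists against 2 cannot give an exact permutation p below 0.333. Sharing between lists is the share of covered bases in common (the Jaccard index). Agreement in direction between the experiments was tested with Fisher's exact test, two-sided, on regions called in exactly 1 list of each experiment. Regions are not independent replicates, and these p-values cover counting only. Intervals are 95% intervals, for counting error only, and those of location shares are Wilson intervals.

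Gene positions came from a RefSeq gene table of the same build, with 21887 protein-coding genes. The table used here gives no strand, transcription start or exon. The planned promoter window was therefore replaced by a window of 1 kb either side of both ends of a gene, called a gene end here, and the planned nearest transcription start by the nearest gene end within 100 kb. Regions were classed as at a gene end, else in a gene body, else intergenic, in place of exons and introns. Planned motif tests were not run, because no genome sequence was used here.

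The 15 gene lists with 264 entries (260 genes, all matched) were fixed before the data were examined. The results of 1 of these lists, and of 1 gene of another, are not reported here, and adjustments and counts of lists are over all 15. Calls at gene ends in all 4 lists were compared between the genes of a list and all other protein-coding genes. The direction of linked regions was compared between a list's regions and the rest among dDAVP-only and vehicle-only regions. Both used Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 15 lists. Named genes were also fixed before the data were examined. They are members of the gene lists, the 10 dDAVP-only and 10 vehicle-only regions with the highest value of the smaller of their 2 within-list percentiles of fold, the 5 genes with the most linked regions of each class, and the 5 regions with the highest mean percentile among those in all 4 lists.

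Alternatives fixed before the data were examined were a -log10 q of at least 5, a fold of at least 5, lists of equal length, lists of equal length within each experiment, a 50% overlap, windows of 500 bp either side of a peak's midpoint, merging within 1000 bp, leaving out each list, gene-end windows of 2500 bp, and links within 20 kb or by gene body and 500 kb. Midpoints replaced summits, which broad mode does not give. Lists of equal covered bases, shared bases as a share of the smaller list, fixed windows for genomic location, and equal-length lists for covered bases around a gene were added after seeing the data.

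A ranking of the regions shared by all 4 lists was also added after seeing the data, with the peaks of Aqp2 already known. Within each list, the same regions were ranked by a summary of their peaks, and the vehicle percentile was subtracted from the dDAVP percentile in each experiment. The 4 summaries tried were the length-weighted mean fold, the highest fold, the fold above 1 times length, and the covered bases. Each of the 4 is reported. Gene lists were tested on the mean shift of their genes against 100000 random gene sets drawn with replacement, in a two-sided permutation test with Benjamini-Hochberg adjustment.

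The counting of regions was tested on simulated lists of the real lengths, with 100 regions planted in each direction among 60000 over 20 draws. The spreads of the simulated signal were fixed values, the same for all lists, and were not fitted to the data. Simulated regions lay apart, so peaks of different regions did not merge. Planted regions were set above the calling limit in the lists of their treatment and far below it in the others. With deposited lengths, 100% of the planted regions were recovered in both directions, which this setting fixed in advance. With equal lengths, 87.7% of the dDAVP-only and 78.0% of the vehicle-only ones were recovered. With nothing planted, the median odds ratio of agreement was 1.05 at deposited lengths and 1.00 at equal lengths. The gene list test, on 15 simulated lists of 15 genes, called 88.3% of the shifted and 2.5% of the unshifted lists. The shifted lists were moved by a full SD of a gene's shift. The real lists held 3 to 24 genes with a shared region, so the 88.3% does not hold for smaller shifts or smaller lists. Overlaps, covered bases and distances to gene ends were checked against direct counting on 1 chromosome, with 0 differences. Scripts ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1.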

Results

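H3K27ac, a histone mark of active promoters and enhancers, was mapped in mpkCCD collecting duct cells after 24 h with 0.1 nM dDAVP or vehicle (n = 2 experiments each). dDAVP is an analogue of vasopressin, the hormone that raises water permeability of the collecting duct through cAMP. The study asked which acetylated regions differ between the treatments. The lists held 37235 peaks over 99.0 Mb for dDAVP replicate 1, 39745 over 104 Mb for vehicle replicate 1, 20124 over 33.5 Mb for dDAVP replicate 2, and 29597 over 56.9 Mb for vehicle replicate 2. The dDAVP list held 0.937 times as many peaks as the vehicle list in experiment 1 and 0.680 times as many in experiment 2. Peak numbers were 28680 ± 12099 (SD, n = 2) with dDAVP and 34671 ± 7176 (SD, n = 2) with vehicle, and the dDAVP list was shorter in both experiments. The difference within an experiment, vehicle minus dDAVP, was 2510 and 9473 peaks (mean 5992 ± 4924, SD, n = 2 pairs), and was not tested. Labels do not say how far the experiments were separate beyond their number.

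The regions ranked highest in all 4 lists lay at ends of the genes Hoxb5, Tnrc18, Eif3b, Kmt2e and Dclre1a. The Hoxb5 region spanned chromosome 11, 96249878 to 96357522 (mm10), within the Hoxb cluster of developmental transcription factor genes, with the authors' fold between 14.8 and 19.7 in the 4 lists. Gene ends were called in all 4 lists for 9888 of 21887 protein-coding genes (45.2%), and in none for 9819. Among epithelial junction and polarity genes, 19 of 20 were called in all 4 lists, including Cldn3, Cldn4, Cldn7 and Cldn8, which encode tight junction proteins. The same count, 19 of 20, was found for proliferation genes. Housekeeping genes were called for 14 of 15, cAMP-responsive immediate early genes for 17 of 22, with Fos, Fosb and Egr1 among them, and histone acetylation genes for 16 of 21. Each of these 5 lists exceeded the other protein-coding genes (Fisher's exact test, adjusted p between 1.57e-05 and 0.0129).

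Markers of other kidney segments and cell types were called less often. Of 14 proximal tubule markers 2 were called in all 4 lists, of which Lrp2 was 1, and of 10 thick limb and distal convoluted tubule markers 0 were. Fibroblast markers gave 1 of 12, and leukocyte and endothelial markers 1 of 14. All of these 4 lists fell below the other genes (Fisher's exact test, adjusted p between 0.00840 and 0.0424). Principal cell transport genes gave 9 of 16 (Fisher's exact test, adjusted p = 0.486), with Aqp2, Aqp3, Avpr2, Scnn1a, Scnn1g and Hsd11b2 among those called in all 4. Scnn1b and Nr3c2 were called only in the lists of experiment 1, and Kcnj1 only in those of experiment 2. Of 14 intercalated cell markers 5 were called (Fisher's exact test, adjusted p = 0.595), of 20 collecting duct transcription factor genes 14 (adjusted p = 0.0550), of 30 cAMP and protein kinase A signalling genes 19 (adjusted p = 0.0808), and of 16 glucocorticoid-responsive genes 10 (adjusted p = 0.242). The transcription factor list passed at equal length (Fisher's exact test, adjusted p = 0.0368) and at a -log10 q of at least 5 (0.0435). The cAMP list passed with windows of 2500 bp (Fisher's exact test, adjusted p = 0.0108) and at a -log10 q of at least 5 (0.0334). Gata3, Pax2, Pax8, Elf3 and Cebpb were called in all 4 lists, and Foxi1, a transcription factor gene of intercalated cells, in none. Gene ends were used in place of promoters, so a call can lie at either end of a gene.

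**Figure D1:**
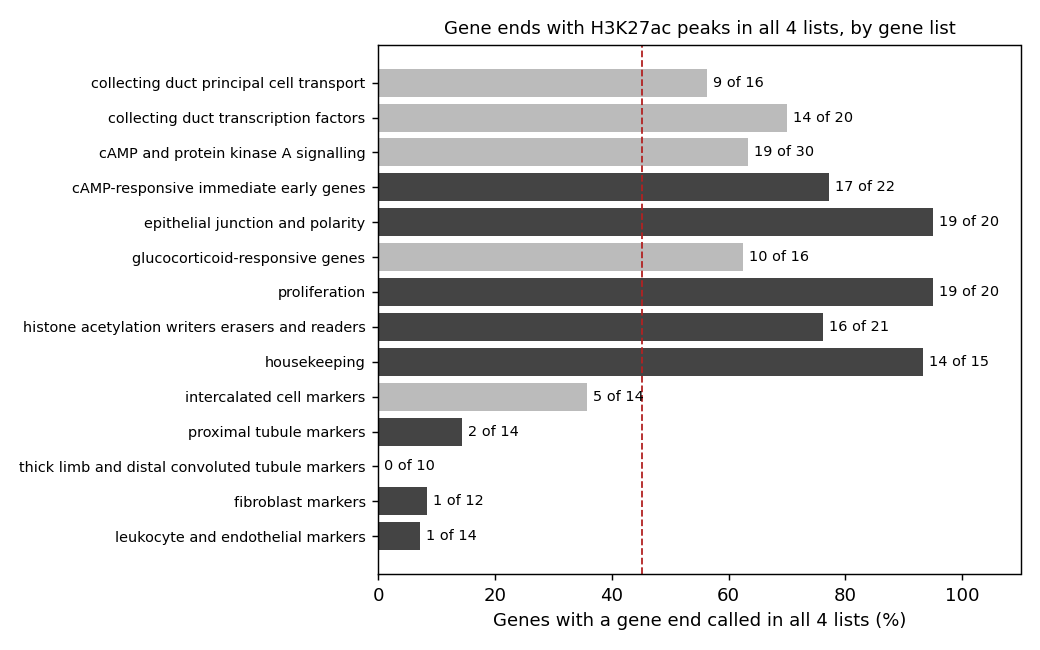
Bars give the percent of each list's genes with a gene end called in all 4 peak lists, with the counts beside them, and the dashed line marks 45.2% of all protein-coding genes. Dark bars differ from the other genes at an adjusted p under 0.05; junction genes reach 19 of 20 and thick limb and distal convoluted tubule markers 0 of 10.

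Lists sharing an experiment had a mean Jaccard index of 0.616, lists sharing a treatment 0.410, and lists sharing neither 0.399. Unequal covered lengths limited this index to means of at most 0.770, 0.443 and 0.448. As a share of the smaller list of a pair, the means were 0.894, 0.955 and 0.939, so the order turned. Of the peaks of dDAVP replicate 2, 97.7% overlapped a peak of vehicle replicate 2, 98.4% a peak of dDAVP replicate 1 and 98.9% a peak of vehicle replicate 1. With 2 pairs of each kind no test was made. In lists cut to equal covered bases the mean indices were 0.626, 0.402 and 0.393. The shares of the smaller list were then 0.769, 0.572 and 0.563, so the same experiment came first by both measures. The share of the smaller list and the equal covered bases were chosen after seeing the data.

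Few regions were called by treatment. Of 45705 union regions, 16537 were called in all 4 lists, 29 were dDAVP-only and 1149 vehicle-only. The top dDAVP-only region lay 15302 bp from an end of Pde10a, a gene of a cyclic nucleotide phosphodiesterase (chromosome 17, 8505035 to 8509885, intergenic). The authors' fold there was 2.94 and 3.81, at percentiles 46.3 and 47.9 of the dDAVP lists, so below the middle of both. This region was followed by those nearest Ksr2, Gm5820, Nod1, Myrfl, St8sia6, Nek6, Slc25a13, Wars and Rad21, the last at a smaller percentile of 19.7. At equal length 4 of these 10, those nearest Ksr2, Gm5820, Myrfl and St8sia6, were dDAVP-only, and that of Pde10a was called in dDAVP replicate 2 alone. The vehicle-only regions were led by those nearest Cnmd, Pabpc2, Cftr (the chloride channel gene), Fhad1, Usp31, Asb5, Adk, Vwa8, Gm6619 and Ckb. All 10 were vehicle-only at equal length too. Shortening a list can only remove calls, and these 10 were picked for high percentiles, the smaller being at least 51.6. Their recurrence therefore follows largely from that choice, and 10 of 10 against 4 of 10 does not compare the classes. The Cftr region lay in the gene body (chromosome 6, 18270829 to 18272149), with fold 3.80 and 3.95 in the vehicle lists. Apbb2 had 4 linked vehicle-only regions, and Arid5b, Adamts5, Serp2 and Gadd45g had 3 each. At equal length Apbb2 and Serp2 had 1 and the other 3 had 0. No gene had more than 1 linked dDAVP-only region. At equal length the highest number per gene was 2 in both classes. Smim3, Lratd1, Mtus1 and Lrrc8d then had 2 dDAVP-only regions each. Genes with 2 vehicle-only regions included Fam110b, Capzb, Col4a2, Ksr1 and Efl1.

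These counts changed when the lists were shortened. In simulated lists of the deposited lengths with no effect, the medians were 17 dDAVP-only and 848.5 vehicle-only regions, and at equal length 244.5 and 250. The spreads in these lists were not fitted to the data. The medians therefore show that unequal lengths alone can unbalance the classes, and give no measure of an excess. In lists of equal length there were 202 dDAVP-only and 362 vehicle-only regions, and in lists of equal length within each experiment 59 and 278. Of the 29 dDAVP-only and 1149 vehicle-only regions, 7 and 46 overlapped a region of the same class at equal length, so most regions of those classes were different ones. With lists cut to equal covered bases, chosen after seeing the data, there were 112 dDAVP-only and 0 vehicle-only regions, so the balance between the classes turned. That setting kept 20124 peaks of dDAVP replicate 2 and 7068, 6917 and 11642 of dDAVP replicate 1, vehicle replicate 1 and vehicle replicate 2. The dDAVP-only count was 104 without dDAVP replicate 1, 219 without vehicle replicate 1, 5464 without dDAVP replicate 2 and 66 without vehicle replicate 2. The vehicle-only count was 7104, 3175, 1293 and 8231 in the same order. Splitting the 4 lists by experiment gave 7296 regions for experiment 1 and 63 for experiment 2, and the crossed split gave 233 and 14. At equal length these were 1483 and 492, and 171 and 116.

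**Figure D2:**
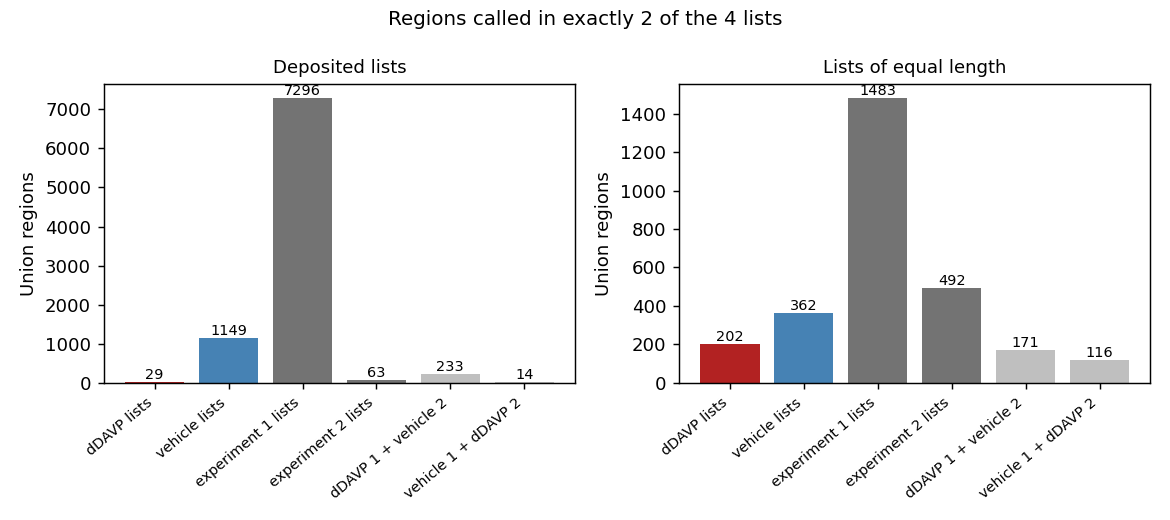
Bars count the union regions called in exactly the named pair of lists and in no other, for the deposited lists (left) and for lists of equal length (right). Pairs of the same treatment held 29 and 1149 regions in the deposited lists, and 202 and 362 at equal length, while the pair of experiment 1 held 7296 and 1483.

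The direction of regions called in exactly 1 list of each experiment was associated between the experiments. Of these, 29 were called with dDAVP in both and 1149 with vehicle in both, against 233 and 14 that changed sides. The same way was taken by 1178 of 1425, where the numbers called in each list alone give 1136 with no association. The odds ratio was 10.2 (95% interval 5.32 to 19.6, Fisher's exact test, p = 8.26e-13). At equal length it was 3.69 (2.75 to 4.94), from 202 and 362 against 171 and 116 regions, with 564 of 851 the same way against 438.8. At equal covered bases it was 0, with an interval of 0.0176 to 7.87, since there were 0 vehicle-only regions.

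Regions called by treatment overlapped gene ends less often than regions in all 4 lists. Of the regions in all 4 lists, 54.0% overlapped a gene end, 23.4% lay in a gene body and 22.6% were intergenic. Of the dDAVP-only regions 0 of 29 overlapped a gene end (Wilson upper bound 11.7%), and of the vehicle-only regions 97 of 1149 (8.44%). Both differed from the regions in all 4 lists (Fisher's exact test, p = 1.76e-10 and p = 1.88e-224). dDAVP-only and vehicle-only regions did not pass the test against each other (p = 0.163). Low shares were not particular to these classes, and were, with no test made, 4.86% of regions in crossed pairs of lists, 10.8% in pairs of the same experiment and 6.07% in 1 list. Regions in all 4 lists were wider, with a median of 3476 bp against 1412 bp for dDAVP-only and 1153 bp for vehicle-only regions. At equal length the shares were 8.42% and 16.9% (odds ratio 0.453, Fisher's exact test, p = 0.00507), and with fixed windows, chosen after seeing the data, the odds ratio was 1.11, on the other side of 1 (p = 0.682).

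Linked regions were too few to compare the gene lists in the direction of vehicle. None of the 29 dDAVP-only regions and 20 of the 1149 vehicle-only regions were linked to a gene of the lists (Fisher's exact test, adjusted p = 1 for all 15 lists, and 0 lists at an unadjusted p under 0.05). At a share of 20 in 1149, 0 of 29 shows no difference between the classes. At equal length 9 treatment-only regions were linked, with dDAVP-only ones among them, and 0 lists passed. With 97.5% of the treatment-only regions being vehicle-only, lists of 0 to 3 such regions could not pass towards vehicle. Ccnd1, which encodes cyclin D1 of the cell cycle, was the only gene of the lists whose gene end was called in both vehicle lists and no dDAVP list. That region spanned 6191 bp (chromosome 7, 144937243 to 144943433), with fold 2.97 and 3.35. It was 1 of 91 such genes among all 21887, and at equal length its gene end was called in vehicle replicate 2 alone. Ccnd1, Prkar1b, a regulatory subunit gene of protein kinase A, Nedd4l, a ubiquitin ligase gene of sodium channel control, and Atp6v1g3, an intercalated cell gene, had 2 linked vehicle-only regions each. At equal length Prkar1b had 2 and the other 3 had 0. Only 1 of the Prkar1b regions was the same one (chromosome 5, 139043007 to 139044430). When a list had to cover at least 50% of a region, 1 of the 15 lists passed. This was cAMP and protein kinase A signalling, with 3 of 35 dDAVP-only regions and 4 of 1463 vehicle-only regions (Fisher's exact test, adjusted p = 0.00576). The 3 regions were near or in Crem, Pde4a and Pde4b, and under the 1 bp rule none of them was dDAVP-only. Crem lay close to the limit, with 47.1% and 46.4% covered in the vehicle lists, as did Pde4b, with 52.4% in dDAVP replicate 2. Of the 4 vehicle-only regions, 3 were linked to Prkar1b.

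Aqp2, the vasopressin-regulated water channel gene of principal cells (chromosome 15, 99579056 to 99584545), was covered by called peaks in all 4 lists. In dDAVP replicate 1, 1 peak of 18089 bp spanned the gene, with fold 6.54 at percentile 87.9 of its list, and in vehicle replicate 1 a peak of 12985 bp had fold 3.93 at percentile 64.6. In dDAVP replicate 2, peaks of 5893 and 5899 bp had fold 4.36 and 4.23, at percentiles 60.9 and 58.1. In vehicle replicate 2, peaks of 2803, 1497 and 2166 bp had fold 2.78, 4.85 and 2.71, at percentiles 25.1, 68.8 and 21.4, so the highest percentile in experiment 2 was that of a vehicle peak. Covered bases within 10 kb of the gene were 21693 with dDAVP and 18388 with vehicle in experiment 1, and 14676 and 10594 in experiment 2. The ratios, 1.18 and 1.39, were both above 1, as for 357 of 12558 genes covered in all 4 lists, while 6452 had less with dDAVP in both. This measure was chosen after the peaks of Aqp2 had been seen, and 43 genes had a larger value of the smaller ratio. At equal length the ratios were 1.16 and 3.56, as 4123 bp stayed covered in vehicle replicate 2, 564 of 12293 genes were above 1 in both, and 123 had a larger value. Within experiments dDAVP exceeded vehicle by 3305 and 4082 bp (mean 3694 ± 549, SD, n = 2 pairs). The exact permutation test within pairs gave p = 0.5, two-sided, the smallest p that 2 pairs can give, and without pairing p = 0.667.

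**Figure D3:**
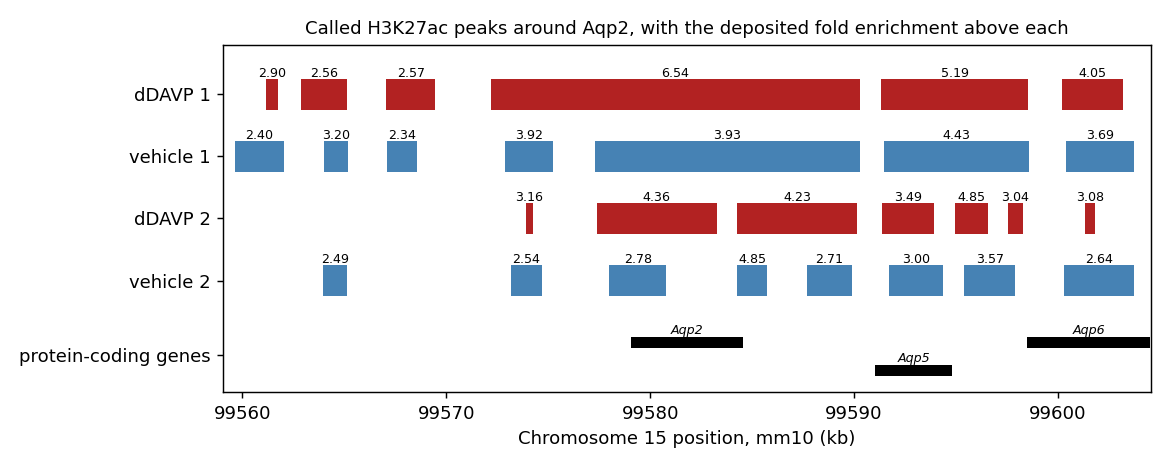
Boxes are the called peaks on chromosome 15 (kb, mm10) around Aqp2 in the 4 lists, with the authors' fold above each, and black bars are protein-coding genes. One peak spans Aqp2 in both lists of experiment 1, of 18089 bp with dDAVP and 12985 bp with vehicle, and separate peaks lie over and beside it in both lists of experiment 2.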

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

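Lists of equal length were planned as an alternative, but their use to weigh these patterns was chosen after the results had been seen, as were lists of equal covered bases and the test of enrichment. The stratified test of agreement was not. Peaks outside the assembled chromosomes, which the comparisons do not use, numbered 22 in dDAVP replicate 1, 11 in vehicle replicate 1, 5 in dDAVP replicate 2 and 12 in vehicle replicate 2, each above the 3 that a count of 0 allows. Groups of 2 samples allowed no search for outlying samples.

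The direction of regions called in exactly 1 list of each experiment was associated between the experiments. Of these, 1178 of 1425 went the same way, against 1136 with no association. Unequal numbers of peaks are argued against by the lists of equal length, where the lower bound of the odds ratio was 2.75. Those lists still covered 78.4 Mb with dDAVP and 80.8 Mb with vehicle in experiment 1, and 33.5 and 48.5 Mb in experiment 2. This cut therefore cannot decide on unequal covered bases. Region width and signal strength are argued against by a Mantel-Haenszel odds ratio over 16 strata of both, which was 3.49 with a lower bound of 2.55. Both use cuts by number of peaks, after which 7 of the 29 dDAVP-only and 46 of the 1149 vehicle-only regions kept their class, so they bear on mostly other regions. At equal covered bases the odds ratio was 0, with an interval of 0.0176 to 7.87. A treatment effect and any other difference that recurred between the treatments in both experiments, such as the smaller covered length with dDAVP, stay open.

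Vehicle-only regions outnumbered dDAVP-only regions in the deposited lists, 1149 to 29. Simulated lists of those lengths with no effect gave medians of 848.5 and 17. Their spreads were not fitted to the data, so the difference from these medians is no measure of an excess. The vehicle-only share was 64.2% at equal length (exact 95% interval 60.1 to 68.1%) and 0% at equal covered bases (0 to 3.24%). The second interval met neither outcome written down for this test, and the setting left dDAVP replicate 2 with the most peaks, 20124 against 6917 to 11642. No lists without an effect were simulated for that setting. Shorter dDAVP lists therefore cannot be told apart from a loss of acetylation with these cuts. Weaker enrichment in the dDAVP immunoprecipitations cannot be told apart from treatment either, since covered bases were 0.951 and 0.590 times those of vehicle. Per the file headers, the redundant rate of immunoprecipitated tags was also higher with dDAVP in both experiments. It was 0.11 with dDAVP and 0.08 with vehicle in experiment 1, and 0.18 and 0.13 in experiment 2. Its part in the list sizes was not tested.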

How the results depend on the processing

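Lists of equal covered bases, the share of the smaller list, fixed windows for location and the summaries of the ranking were chosen after seeing the data. The odds ratio of agreement stayed above 1 and past the threshold in 7 of the 8 alternatives with a value, between 2.74 (fold of at least 5) and 12.7 (50% overlap). It was 0 at equal covered bases, where the class counts were 112 and 0; the cause was not tested. Under the replicate block, where the experiment number pairs the lists, it was 8.14, with 59 dDAVP-only and 278 vehicle-only regions. The dDAVP-only count was 9 at a -log10 q of at least 5, 9 at a fold of at least 5, 202 at equal length and 197 with fixed windows, against 29. The vehicle-only count was 689, 497 and 362 in the first 3 of these, against 1149. Leaving out 1 list gave 66 to 5464 dDAVP-only and 1293 to 8231 vehicle-only regions, since 1 fewer list then sets the class, and the agreement has no value there. Sharing at 50% overlap, as a share of regions, was 0.446 for the same experiment, 0.272 for the same treatment and 0.259 for neither. As a share of the smaller list it was 0.894, 0.955 and 0.939, in another order. At equal covered bases, where list sizes do not limit the Jaccard index, that index was 0.626, 0.402 and 0.393. The share of the smaller list was then 0.769, 0.572 and 0.563, so the same experiment came first by both measures. The gene-end odds ratio of dDAVP-only against vehicle-only regions was 0 at 2500 bp (Fisher's exact test, p = 0.0411), 0.453 at equal length and 1.11 with fixed windows; the cause was not tested. Both classes stayed below the regions in all 4 lists in all 4 alternatives. Between 7 and 8 gene lists had more gene ends called in all 4 lists, against 6, and 4 had fewer in every setting. The odds ratio of principal cell genes was 0.803 at a -log10 q of at least 5, against 1.56, past the threshold in neither; the cause was not tested. Linked regions gave 1 list at 50% overlap and 0 in the other 4 alternatives. Ranking by covered bases gave 1 shifted list (permutation test, adjusted p = 0.00180), the thick limb and distal convoluted tubule markers, with 4 genes at -21.4 percentile points, against 7.51 by mean fold, 6.20 by highest fold and -6.98 by fold above 1 times length, and the other 3 summaries gave 0; the cause was not tested. Motif alternatives (window, GC content, list length) were not run. With no read counts used here, depth limits every statement about a region that was not called.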

Other observations

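The ranking of shared regions was designed after seeing the data, with the peaks of Aqp2 already known, and the test of the gene list was chosen after its regions had been looked at. The 2 tests of the correlation of shifts were not. The 16537 regions called in all 4 lists were ordered by the smaller of their shifts in the 2 experiments. A region in the body of Pde4b, the gene of a cAMP phosphodiesterase, came first among upward shifts under all 4 summaries. It lies on chromosome 4, 102509711 to 102513786, 93489 bp from an end of the gene. Ranked by mean fold, its percentile among these regions was 44.0 higher with dDAVP than with vehicle in experiment 1 and 61.2 higher in experiment 2. In experiment 1 alone the Aqp2 region shifted more, by 51.6. The mean and highest fold of the Pde4b region were the same in each list, so these 2 summaries are not separate measurements of it. The Pde4b region was covered over 100% and 52.4% of its length in the dDAVP lists and over 22.4% and 18.7% in the vehicle lists. It was 1 of the 3 regions linked to cAMP and protein kinase A genes that were dDAVP-only at 50% overlap, with those of Crem and Pde4a, so the 2 observations are not independent.

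The place of the Aqp2 region depended on the summary. Ordered by the smaller of its 2 shifts, it was 2nd by mean fold, with shifts of 51.6 and 43.3. It was 1021st by highest fold, 915th by fold above 1 times length and 4511th by covered bases. Its high place therefore rests on 1 of the 4 summaries tried. By mean fold and the same order, regions of Baiap2l2, Arhgef3, B3gnt7, Cmtm6, Armc9, Spout1 and Lifr came next. Regions nearest Col4a1, Arl4c, Dipk1a, Smarcal1 and Ap4s1 led the downward shifts. These genes were chosen after their values were seen.

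Shifts in the 2 experiments were weakly related across regions, which are not independent replicates. Spearman's correlation was 0.163 by mean fold, and 0.134, 0.264 and 0.171 by highest fold, fold above 1 times length and covered bases. By mean fold, 55.3% of regions shifted the same way in both. Region width and signal strength are argued against as the whole source, since the correlation was 0.169 after the means of 100 strata of both were removed. Overlap with a gene end is argued against as the whole source too, since the correlation was 0.0982 at gene ends and 0.233 elsewhere. It was higher elsewhere, and distance among those regions was not tested, so a part played by distance stays open. A shared effect of treatment may contribute, but any technical difference between the treatments that recurred in both experiments stays open and was not tested.

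A hypothesis on a gene list did not pass its test. Regions of cAMP and protein kinase A signalling genes were hypothesised to shift up together, and the mean shift of 24 genes by mean fold was 2.20 percentile points (permutation test, adjusted p = 0.492). The lowest adjusted p among the 15 lists by mean fold was 0.306. Among the lists at that value were principal cell transport genes. Of their 12 genes with a shared region, 5 shifted up in both experiments and 2 down. Aqp2, whose peaks were already known, had a mean shift of 47.5. The list had a mean shift of 5.44 and an unadjusted p of 0.0232 in the permutation test. By the other summaries, highest fold, fold above 1 times length and covered bases, it was 0.155, 0.987 and 0.367, with a shift of -0.966 by covered bases. Leukocyte and endothelial markers, with 4 genes, had a shift of -8.32 and an unadjusted permutation p of 0.0416. By the other summaries in the same order it was 0.103, 0.177 and 0.594, with a shift of -0.726 by covered bases.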
